A study of Mus musculus with 12 samples.

How the data were processed

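ChIP-seq libraries were made from spermatogenic cells of mouse testes at postnatal day 18. Per the labels' protocols, tubules were digested with collagenase and trypsin, the cells were passed through a 40 micron filter and fixed in 0.3% formaldehyde for 30 min, and chromatin was cut with micrococcal nuclease before precipitation. Micrococcal nuclease favours open and AT-rich linker DNA, so peak outlines reflect nucleosome positions as well as protein binding. The libraries were grouped by their titles into INO80 ChIP, H2A.Z ChIP with wild-type Ino80, H2A.Z ChIP with deleted Ino80 and the input of each, with 2 libraries in every group. The labels do not say whether the libraries of a group came from different animals.

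The files analysed here are 3 peak lists, 1 per ChIP group, which the authors deposited with 3 columns (chromosome, start and end) and no score, fold, p-value or summit. Bowtie2, SAMtools, deepTools and MACS2 and the genome build mm10 are named in the submitters' processing notes, without versions. The role of each tool, the peak threshold, the control used and the way the 2 libraries of a group were combined are not given in the sources used here. The smallest peak in every list is 147 bp wide and the smallest gap between neighbouring peaks is 251 bp. Input libraries and values per library were not analysed here. Because whether a peak is listed depends on depth and on the peak threshold, a peak present in 1 list and absent from another can differ in strength by little, and the unknown depth per library sets no stated precision. Peak width stood in for strength wherever a ranking was needed. It is an imperfect measure of strength, and widths were ranked within a list. The exception is the matched comparison of knockout-only with wild-type-only regions, which used widths in bp across both lists.

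Gene positions came from the NCBI RefSeq gene table of GRCm38.p6, the assembly that mm10 names, which gives the start and end of each gene without strand. Transcription start sites were therefore not used. The intended promoter window of 1 kb on both sides of a start site was replaced by 1 kb on both sides of either annotated end of a protein-coding gene, called a gene end here. A peak at a gene end can thus lie at the start or the 3 prime end of a gene. Of genes over 5 kb with a peak at an end, 95.1% had INO80 at 1 end and not the other (94.6% for wild-type and 95.9% for knockout H2A.Z). There were 21887 protein-coding genes on chromosomes 1 to 19, X and Y, of which 14839 had no other gene end within 2 kb.

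Peaks were compared by overlap of at least 1 bp. INO80 peaks were shuffled 1000 times within their chromosome, between the first and last annotated gene; assembly gaps were not left out. Overlapping H2A.Z peaks of both genotypes were joined into regions, each called wild type only, shared or knockout only. INO80 in these classes, and in genes classed in the same way, was compared by Fisher's exact test, two-sided, with exact conditional 95% intervals. The 11 gene lists (416 entries, 415 distinct genes, since Eomes stands in 2 lists, 4 matched through an older symbol) were fixed before the data were examined, as were the groups, the main tests, most alternative settings and the rule for naming genes. Each list was tested for 4 quantities against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 11 lists within each quantity and a threshold of 0.05. Width percentiles were compared by permutation tests with 100000 resamples. Odds ratios within strata used the Mantel-Haenszel estimate, over 10 width groups with 2 exceptions. Knockout-only against wild-type-only regions used fixed bins of width in bp. The X-linked comparison within genes with and without INO80 used no width groups.

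The genes named are Ino80, H2az1 and H2az2; the 10 with the widest INO80 peak at a gene end; the 10 each with the widest wild-type-only and knockout-only H2A.Z peak; and from each list up to 4 members with the widest INO80 peak and up to 3 members of each changed class. Predicted genes, Rik genes and multigene copies were passed over outside the lists. Genes named under the rule for partners outside the window were chosen after their values were seen. Single genes that the rule names but the text leaves out are not reported here.

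Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Overlap counts were checked against bedtools 2.31.1 and were equal for 6 of 6 pairs of lists, as were the 35393 joined regions. The tests were tested on simulated data. For gene lists with a true odds ratio of 4, 97.5% of 200 intervals held the truth, and with a true odds ratio of 1, 4.5% of 200 tests gave a p under 0.05. The simulated lists had 200 genes each, more than any list tested here. For randomly placed peaks the shuffle test gave a p under 0.05 in 5.0% of 20 runs. Those peaks were placed in the same way as the shuffles, so the runs say nothing about clustered peaks or assembly gaps. With width as a confounder and a true odds ratio of 2 for lost against kept wild-type peaks, the Mantel-Haenszel median was 2.00 and 94.0% of 400 intervals held the truth, while the median without matching was 0.512. Loss and INO80 were drawn there from the same width groups that the test used, without gene-end class. This check therefore concerns the estimator and not how well width stands for strength.

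Alternatives were an overlap of 50% of the shorter interval, a gap of up to 500 bp, the widest 50% of peaks, H2A.Z lists of equal length, the widest 50% of 1 H2A.Z list against the full other list, windows of 500 bp and 3 kb, gene-end and distal regions apart, width as a model term, autosomes alone and a local shift of peaks. Base composition, motifs and the most upstream start site were left out for want of sequence and strand.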

Results

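INO80 and the histone variant H2A.Z were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in spermatogenic cells of mouse testes at postnatal day 18, when the first wave of germ cells has entered meiosis. INO80 is the ATPase of a chromatin remodelling complex that can exchange H2A.Z in nucleosomes, and H2A.Z is a variant of histone H2A found near promoters and enhancers. The 12 libraries fall into 6 groups of 2. INO80 was precipitated from wild-type cells, and H2A.Z from cells with wild-type Ino80 and from cells in which Ino80 was deleted in the testis with Stra8-Cre, a recombinase driven from a gene of premeiotic germ cells. Each of these 3 ChIP groups has a group of input libraries. The data analysed here are 3 peak lists, 1 for each ChIP group. The INO80 list holds 18139 peaks with a median width of 678 bp, the wild-type H2A.Z list 33827 peaks of 460 bp and the knockout H2A.Z list 26199 peaks of 422 bp. Each list stands for 2 libraries and gives positions alone, so no value below has a replicate error and the read depth behind the lists is unknown. Intervals are 95% intervals (Wilson for percentages, exact for odds ratios unless named otherwise) that cover counting error only, and the tests, over peaks, regions or genes, compare lists and not animals. Neighbouring peaks and genes are not independent, so the p-values are smaller than independent units would give. The peak lists hold no value that shows the deletion itself.

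The first question was where INO80 sits in wild-type spermatogenic cells. INO80 peaks lay within 1 kb of an annotated end of 11936 of 21887 protein-coding genes (54.5%, 53.9 to 55.2%). The 10 genes with the widest INO80 peaks at a gene end included Skor1, a transcriptional corepressor (chromosome 9, peak 63141710 to 63151534, 9825 bp), Ebf2 (chromosome 14, 67228965 to 67237859, 8895 bp), Lbx1 (chromosome 19, 45229117 to 45236977, 7861 bp) and the signalling gene Wnt7b (chromosome 15, 85575345 to 85583120, 7776 bp). Neurog3 (chromosome 10, 62127425 to 62135161, 7737 bp), Olig2 (chromosome 16, 91220883 to 91228580, 7698 bp) and Lhx5 (chromosome 5, 120433792 to 120441121, 7330 bp), which all encode transcription factors, were also among them. The other 3 were Tnrc18 with a peak of 10631 bp, the epidermal gene Flg with 13113 bp, all of it within the gene, and Gas8, whose 19465 bp peak lies over the neighbouring 5S ribosomal RNA genes. Of the INO80 peaks, 11671 of 18139 (64.3%, 63.6 to 65.0%) touched a gene end, against a mean of 4.58% when the peaks were placed at random on their chromosomes (range of 1000 shuffles 4.17 to 5.11%, one-sided permutation p = 0.001, the smallest these shuffles can give). Moving each peak by only 5 to 20 kb gave a mean of 10.9%, and the observed share stayed 5.89 times higher.

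With 1 kb windows INO80 was most frequent at developmental regulators, a list of Hox genes and other patterning factors fixed before the data were examined. Of its 70 genes, 69 held INO80 (odds ratio against all other protein-coding genes 57.8, 10.04 to 2318; Fisher's exact test with Benjamini-Hochberg adjustment over 11 lists, adjusted p = 2.43e-16). With 500 bp windows the odds ratio was 8.33 (3.81 to 21.6), below those of polycomb complex (15.7), ribosomal protein (11.4) and histone methylation genes (8.61). With 3 kb windows it was 48.3, against 56.6 for ribosomal protein genes, so the order of the lists depended on the window. Polycomb complex genes followed in the 1 kb windows with 35 of 36 (exact test, adjusted p = 8.91e-08), among them Phf19 with a peak of 2712 bp, Epop with 2574 bp and Cbx2 with 2185 bp. Histone methylation enzymes held INO80 at 29 of 31 genes (exact test, adjusted p = 1.14e-05), with the widest peaks at the histone H3 methyltransferases Nsd1 (3850 bp) and Setd1b (2413 bp). Cytosolic ribosomal protein genes held it at 37 of 40 (exact test, adjusted p = 7.97e-07) and genes of the INO80, SRCAP and H2A.Z machinery at 23 of 27 (adjusted p = 0.00318). In the latter group the peak at Yy1, which encodes a DNA-binding partner of the INO80 complex, spanned 2612 bp, and the peak at Ino80 itself 1390 bp. The H2A.Z genes H2az1 and H2az2 held INO80 peaks of 1704 and 425 bp and H2A.Z peaks in both genotypes. At H2az1 the widest wild-type (794 bp) and knockout (483 bp) H2A.Z peaks lay at opposite ends of the gene. That wild-type peak lies in the neighbouring gene Dnajb14 and had no overlapping knockout peak.

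Among germ cell lists, spermatogonial genes held INO80 at 23 of 30 (odds ratio 2.74, 1.14 to 7.57, exact test, adjusted p = 0.0300; 6.25, 2.11 to 25.04, among genes with no other gene end within 2 kb), with wide peaks at Eomes (4463 bp), Ccnd2 (3685 bp), the stem cell factor Zbtb16 (3285 bp) and the GDNF receptor gene Gfra1 (3118 bp). DNA repair genes held it at 24 of 32 (odds ratio 2.504, 1.09 to 6.45, exact test, adjusted p = 0.0328), including Atr (954 bp), a kinase of the damage response, and Rnf8 (898 bp), a ubiquitin ligase of that response. In the exact test this call ended with 3 kb windows (adjusted p = 0.0957) and among genes with no other gene end within 2 kb (adjusted p = 0.139). Genes of meiotic recombination and synapsis held INO80 at 29 of 46 (63.0%, exact test, adjusted p = 0.300), among them Rec114 (3299 bp) and the recombinase gene Dmc1 (961 bp), and genes of the piRNA pathway at 19 of 26 (73.1%, adjusted p = 0.0914), among them Dazl (1545 bp). Neither share differed from that of other genes at this number of genes. Spermiogenesis genes, which act in haploid cells, held INO80 at 15 of 40 (37.5%, odds ratio 0.4996, 0.245 to 0.986, exact test, adjusted p = 0.0521). With 500 bp windows this list passed the threshold of the exact test (odds ratio 0.443, adjusted p = 0.0261). Markers of somatic testis cells held INO80 at 16 of 38 (42.1%, exact test, adjusted p = 0.157). Those with INO80 included the Leydig cell gene Insl3 and the Sertoli cell genes Sox9 (4432 bp) and Wt1 (3949 bp). Most of the 5468 bp peak at Insl3 lies outside that gene, which has another gene end within 2 kb.

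**Figure D1:**
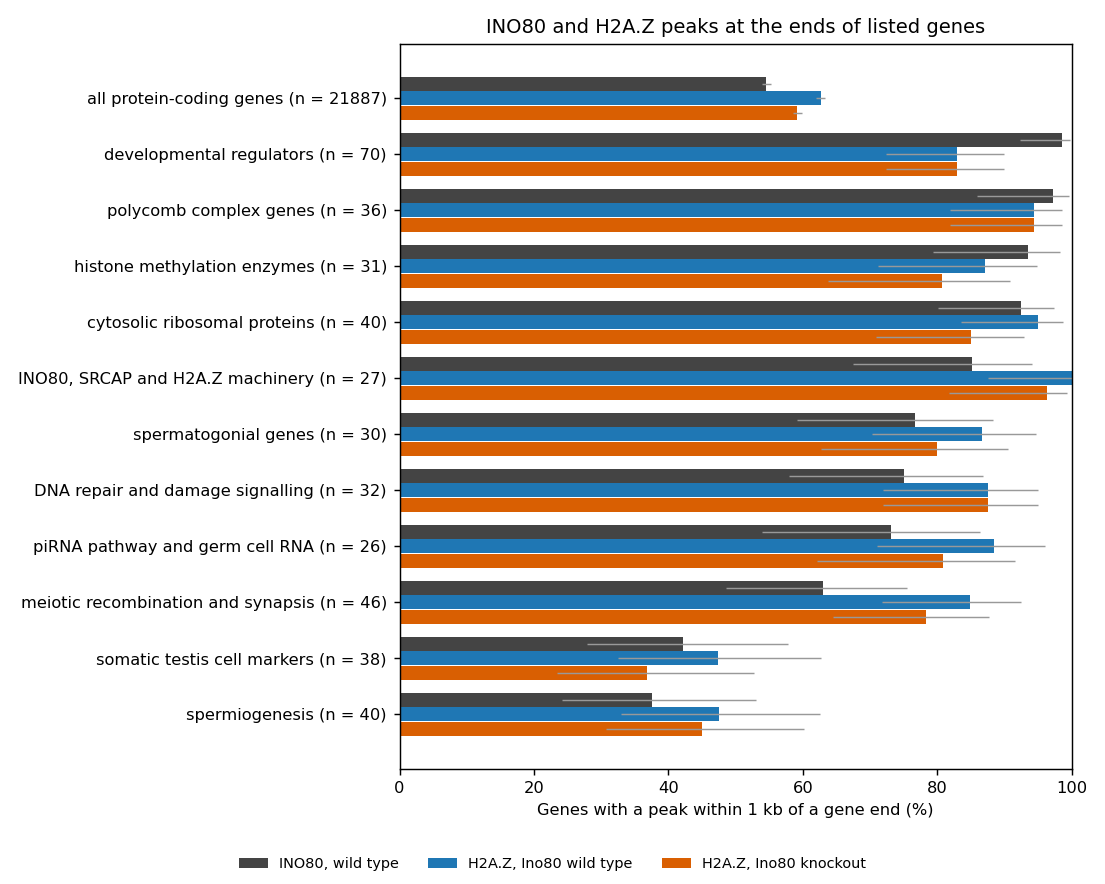
Percentage of genes in each list (x axis) with an INO80 peak (dark grey), a wild-type H2A.Z peak (blue) or a knockout H2A.Z peak (orange) within 1 kb of a gene end; thin grey lines are 95% Wilson intervals and n is the number of genes. INO80 was found at 98.6% of developmental regulators and 37.5% of spermiogenesis genes, against 54.5% of all protein-coding genes.

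The next question was whether INO80 and H2A.Z occupy the same places. Of INO80 peaks, 15051 of 18139 (83.0%, 82.4 to 83.5%) overlapped a wild-type H2A.Z peak by at least 1 bp, against a shuffled mean of 2.04% (1.74 to 2.34%, one-sided permutation p = 0.001, the smallest possible). At gene ends the overlap was 92.4% of 11671 INO80 peaks, and away from them 66.0% of 6468, where shuffles gave 1.11%. H2A.Z was the broader set: 47.2% of wild-type H2A.Z peaks (46.7 to 47.7%) overlapped INO80. Wild-type H2A.Z lay at the ends of 13709 genes (62.6%), and 96.2% of the genes with INO80 also had it. Of the 11 lists, 9 held wild-type H2A.Z more often than other genes (exact test, adjusted p from 3.68e-05 to 0.00862). The INO80, SRCAP and H2A.Z machinery held it at 27 of 27 genes, ribosomal protein genes at 38 of 40, polycomb complex genes at 34 of 36, piRNA genes at 23 of 26, DNA repair genes at 28 of 32, histone methylation enzymes at 27 of 31, spermatogonial genes at 26 of 30, meiotic genes at 39 of 46 and developmental regulators at 58 of 70. Spermiogenesis genes (19 of 40, adjusted p = 0.0560) and somatic testis cell markers (18 of 38, adjusted p = 0.0639) did not pass the exact test. Among genes with no close neighbour the exact test calls for DNA repair genes (adjusted p = 0.198) and histone methylation enzymes (adjusted p = 0.107) ended, as did that for spermatogonial genes with 500 bp windows (adjusted p = 0.0768).

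At the HoxD cluster on chromosome 2 INO80 covered more sequence than H2A.Z. Within 136.9 kb of the cluster there were 23 INO80 peaks covering 31445 bp, 16 wild-type H2A.Z peaks covering 11992 bp and 16 knockout H2A.Z peaks covering 8847 bp. The widest INO80 peak of the cluster (74679022 to 74684635, 5614 bp) spans sequence annotated to Hoxd11 and the start coordinate of Hoxd10.

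**Figure D2:**
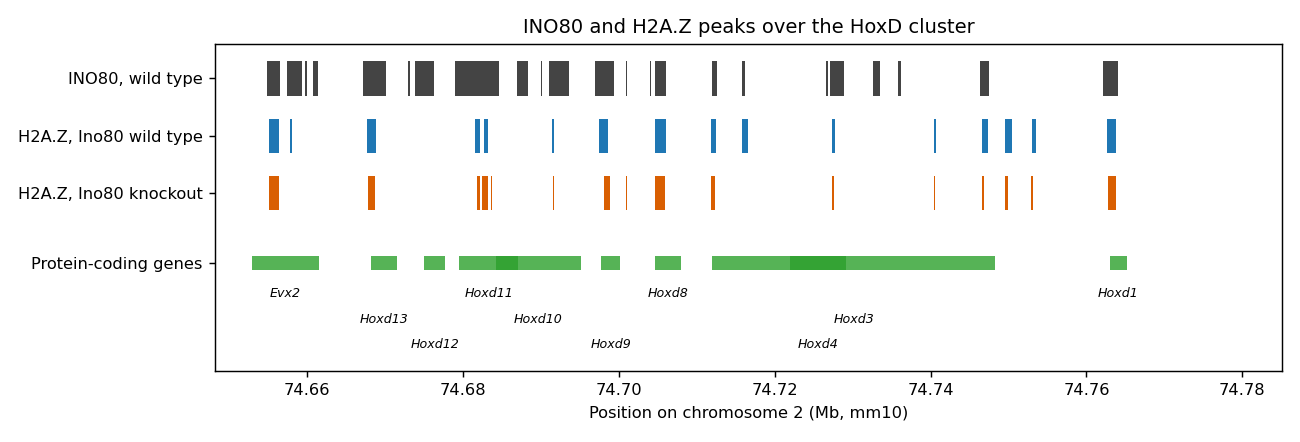
Peaks over the HoxD cluster on chromosome 2 (x axis, position in Mb, mm10), with 1 line each for INO80 (dark grey), wild-type H2A.Z (blue), knockout H2A.Z (orange) and annotated protein-coding genes (green, darker where genes overlap). The 23 INO80 peaks cover 31445 bp, the 16 wild-type H2A.Z peaks 11992 bp and the 16 knockout H2A.Z peaks 8847 bp.

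The main comparison asked how the H2A.Z peak set differs once Ino80 is deleted. Overlapping H2A.Z peaks of both genotypes were joined into regions. Of these, 23485 (66.4%, 65.9 to 66.8%) held peaks of both genotypes, 10173 (28.7%, 28.3 to 29.2%) a wild-type peak alone and 1735 (4.90%, 4.68 to 5.13%) a knockout peak alone. Thus 93.4% of knockout peaks overlapped a wild-type peak and 69.9% of wild-type peaks a knockout peak. Most shared regions touched a gene end (53.5%), whereas 16.5% of wild-type-only and 22.4% of knockout-only regions did. Regions seen in 1 genotype were narrow, with medians of 231 bp (wild type only) and 185 bp (knockout only) against 677 bp for shared regions. Peaks without a partner had a median width percentile of 21.3 in the wild-type list, against 63.7 for partnered peaks, and of 14.6 against 53.1 in the knockout list (permutation tests over peaks, p = 1e-05, the smallest that 100000 resamples can give). Among the widest 50% of wild-type peaks 1259 of 16939 (7.43%) lacked a knockout peak, and among the widest 50% of knockout peaks 46 of 13101 (0.351%) lacked a wild-type peak. The number of regions in a class depends on list length: with the wild-type list shortened to the length of the knockout list by width, 4841 regions were wild type only and 3970 knockout only. This cut removes the narrowest wild-type peaks alone. It lowers the first count and raises the second by construction, so it does not match the lists for depth.

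H2A.Z regions found in the wild type alone held INO80 less often than shared regions. INO80 overlapped 1527 of 10173 wild-type-only regions (15.0%, 14.3 to 15.7%) and 14354 of 23485 shared regions (61.1%, 60.5 to 61.7%), an odds ratio of 0.112 (0.106 to 0.119, Fisher's exact test, two-sided). It was 0.203 (0.188 to 0.220) with the widest 50% of each list and 0.414 (0.385 to 0.445) in a logistic model with the log2 width of the region as a term. Cutting every list, INO80 included, to its widest 50% also leaves peaks unpartnered because their partner was cut. That setting gave 5042 wild-type-only regions, against 1256 for the widest 50% of the wild-type list with the full knockout list. The order was the same near and away from genes: 40.5% against 82.5% at gene ends, and 9.97% against 36.5% elsewhere. Comparing single wild-type peaks of like width and gene-end class gave an odds ratio of 0.383 (Mantel-Haenszel, 0.355 to 0.412). Of wild-type peaks at gene ends, 6.15% of those with INO80 and 30.9% of those without it lacked a knockout peak. Away from gene ends these shares were 17.3% and 52.3%.

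**Figure D3:**
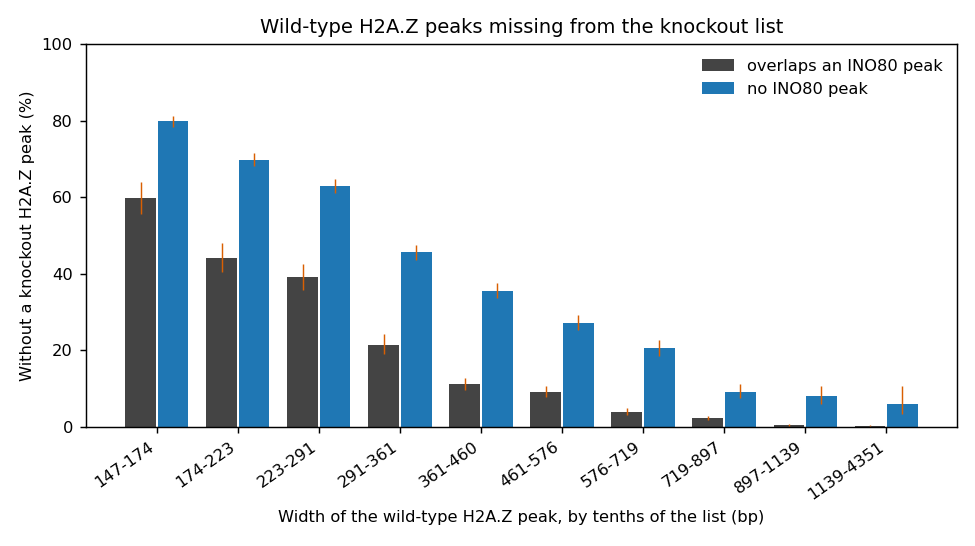
Percentage of wild-type H2A.Z peaks with no overlapping knockout H2A.Z peak (y axis), for 10 equal groups of peaks ordered by width in bp (x axis), with (dark grey) and without (blue) an overlapping INO80 peak; orange lines are 95% Wilson intervals. The share falls from 59.8% to 0.281% with INO80 and from 79.8% to 6.08% without it.

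Regions found in the knockout alone held INO80 in 391 of 1735 cases (22.5%, 20.6 to 24.6%), an odds ratio of 0.185 against shared regions (0.164 to 0.208, Fisher's exact test, p = 6.38e-219). The direction depended on how width was taken into account. A logistic model with the log2 width of the region, which for shared regions spans the peaks of both genotypes, gave 1.48 (1.30 to 1.70), whereas single knockout peaks of like width and gene-end class, a comparison chosen after seeing the data, gave 0.695 (Mantel-Haenszel, 0.612 to 0.789). With the widest 50% of each list the odds ratio was 0.289 (0.251 to 0.332), and with the widest 50% of the knockout list against the full wild-type list, which left 46 regions, 0.0898 (0.0423 to 0.178). The first of these settings counted 1152 knockout-only regions, most of which had a wild-type partner that was cut away. Against wild-type-only regions, a comparison chosen after seeing the data, knockout-only regions held INO80 more often (odds ratio 1.65, 1.45 to 1.87), and among regions of like width and gene-end class the value was 1.74 (Mantel-Haenszel, 1.52 to 1.99). It was 2.11 (1.79 to 2.49) away from gene ends and 1.26 (0.999 to 1.58) at gene ends. These matched values set widths in bp of the 2 lists side by side. Knockout peaks were narrower in general (medians of 488 against 630 bp in shared regions), so like width need not mean like strength.

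At the level of genes, 12806 had H2A.Z at a gene end in both genotypes, 903 in the wild type alone, 143 in the knockout alone and 8035 in neither. With the narrowest wild-type peaks cut to make the H2A.Z lists equal in length, 544 genes were wild type only and 587 knockout only. That cut, too, lowers the first count and raises the second by construction. With the widest 50% of each list there were 1852 and 514. Cutting both lists also removes partner peaks. Against the full other list, the widest 50% left 247 wild-type-only and 18 knockout-only genes. INO80 was present at 86.5% of genes with H2A.Z in both genotypes, 45.4% of wild-type-only genes, 52.4% of knockout-only genes and 4.70% of genes with H2A.Z in neither. The odds ratio of INO80 was 0.130 (0.113 to 0.150, Fisher's exact test, p = 1.77e-168) for wild-type-only genes against genes with H2A.Z in both, and 22.3 (15.6 to 32.0, p = 3.07e-57) for knockout-only genes against genes with H2A.Z in neither. With the widest 50% of each list, where partner peaks were cut away, these odds ratios were 0.383 (0.345 to 0.425) and 5.72 (4.68 to 6.97). Genes with H2A.Z in neither genotype seldom held INO80, since 96.2% of genes with INO80 had wild-type H2A.Z. Wild-type-only genes, at 45.4%, also exceeded their 4.70%, so the second ratio shows nothing particular to the knockout. Wild-type-only and knockout-only genes did not differ detectably from each other (odds ratio 1.33, 0.917 to 1.92, exact test, p = 0.125). In Ino80, the deleted gene, H2A.Z peaks were called in both genotypes (863 bp in the wild type, 487 bp in the knockout), and with 500 bp windows the gene counted as wild type only.

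The genes with the widest peaks in 1 genotype were largely set by the edge of the 1 kb window. The 10 wild-type-only genes with the widest H2A.Z peaks, led by Tchh (4200 bp), Trpv2 (1851 bp), Plcxd1 (1816 bp) and Zfp503 (1773 bp), all had a knockout peak overlapping the same wild-type peak just outside the window. Likewise, 7 of the 10 knockout-only genes with the widest peaks had a wild-type peak overlapping the same knockout peak outside the window, such as Elovl6 (1337 bp), Tbl1x (1287 bp) and Ptpn5 (1235 bp). The other three were the endothelin receptor gene Ednrb on chromosome 14 (knockout peak 103843201 to 103844414, 1214 bp), which had H2A.Z in both genotypes with 3 kb windows, and Ccdc103 and Eftud2, which share 1 knockout peak of 801 bp on chromosome 11. Counting such genes as having H2A.Z in both genotypes, a rule chosen after seeing the data, left 816 wild-type-only and 127 knockout-only genes. Under it the widest wild-type-only peaks lay at Cldn5, a tight junction gene (chromosome 16, 18776386 to 18777825, 1440 bp), Selplg (chromosome 5, 113818399 to 113819786, 1388 bp), the neuronal gene Elavl3 (chromosome 9, 22050899 to 22052174, 1276 bp) and Klf16 (chromosome 10, 80576887 to 80578056, 1170 bp). INO80 was present at Cldn5, Elavl3 and Klf16 and not at Selplg. After Ednrb, Ccdc103 and Eftud2, the widest knockout-only peaks lay at Ghrh (615 bp), Gpx8 (585 bp) and Pycr1 (555 bp), none of which held INO80.

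No gene list passed the threshold for a difference from other genes in the share that had H2A.Z in the wild type alone (0 of 11 lists by Fisher's exact test with Benjamini-Hochberg adjustment, 1 at an unadjusted p under 0.05). Developmental regulators had wild-type-only H2A.Z at 2 of 58 genes, Neurod1 and Hoxa9. Polycomb complex and DNA repair genes had it at 0 of 34 and 0 of 28. Ribosomal protein genes had it at 4 of 38, including Rpl24 (296 bp), and meiotic genes at 3 of 39: Ccnb1ip1 (620 bp), the cohesin gene Rec8 (523 bp) and Terb2 (391 bp), all without INO80. Histone methylation enzymes had it at 2 of 27, the X-linked demethylase genes Kdm5c (212 bp) and Kdm6a (507 bp). Spermatogonial genes had it at 2 of 26 (Lin28a and Rhox13), piRNA genes at 2 of 23 (Tdrd7 and Tex19.1), spermiogenesis genes at 1 of 19 (Izumo1) and the INO80, SRCAP and H2A.Z machinery at 1 of 27 (Mcrs1, 842 bp). With 3 kb windows Neurod1, Hoxa9, Rpl24, Kdm6a, Lin28a and Izumo1 had H2A.Z in both genotypes. Somatic testis cell markers had it at 4 of 18 genes (22.2% against 6.57% of other genes, exact test, unadjusted p = 0.0272, adjusted p = 0.300), among them Myh11 (214 bp) and the Sertoli cell receptor gene Fshr (197 bp).

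For H2A.Z in the knockout alone only genes without wild-type H2A.Z could be tested, and most lists held few of them. No list passed the threshold, and 1 had an unadjusted p under 0.05. That list was developmental regulators, where Hoxd10 (184 bp) and T (147 bp, the smallest peak width in the lists) were 2 of the 12 genes without wild-type H2A.Z (16.7% against 1.73%, odds ratio 11.4, 1.20 to 54.1, exact test, adjusted p = 0.197). It passed the exact test with 500 bp windows (odds ratio 14.8, adjusted p = 0.00353) and with 3 kb windows (46.6, adjusted p = 0.00200). T was knockout only under both, whereas Hoxd10 had no H2A.Z peak within 500 bp and peaks of both genotypes within 3 kb. Olig2 was knockout only with 500 bp windows and had peaks of both genotypes within 1 kb, so the class of both genes was set by the window edge. The INO80, SRCAP and H2A.Z machinery had 0 genes to test, and the other 9 lists had 2 to 21 genes each with 0 knockout only, too few to show a difference from the 1.75% of other genes.

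The sex chromosomes are transcriptionally silenced in pachytene spermatocytes, so X-linked genes were compared with autosomal genes. Fewer peaks of both proteins were listed on the X chromosome. INO80 peaks lay at 235 of 966 X-linked genes (24.3%) and 56.6% of autosomal genes (odds ratio 0.246, 0.211 to 0.287, Fisher's exact test, p = 2.59e-88). Wild-type H2A.Z peaks lay at 36.5% and 64.6% (odds ratio 0.315, 0.275 to 0.361, exact test, p = 1.00e-66). Copy number and read depth of the single X chromosome were not taken into account, so fewer listed peaks need not mean less protein. Peaks per Mb were 2.27 on the X chromosome and 7.30 on autosomes for INO80, 3.05 and 13.7 for wild-type H2A.Z and 2.55 and 10.6 for knockout H2A.Z. Of genes with wild-type H2A.Z, 73 of 353 X-linked (20.7%, 16.8 to 25.2%) and 826 of 13351 autosomal genes (6.19%, 5.79 to 6.61%) lacked it in the knockout list (odds ratio 3.95, 2.98 to 5.18, exact test, p = 5.13e-19). X-linked peaks at gene ends were narrower, with a median of 411 bp against 720 bp on autosomes, and among genes of like peak width the odds ratio was 1.70 (Mantel-Haenszel, 1.25 to 2.31). Among genes of like peak width and INO80 status it was 1.27 (0.931 to 1.74), an interval that includes 1. Counted over all wild-type peaks, 26.3% of X-linked and 30.1% of autosomal peaks lacked a knockout peak. Knockout-only H2A.Z was found at 19 of 613 X-linked genes without wild-type H2A.Z (3.10%) and 1.68% of autosomal ones (odds ratio 1.87, 1.08 to 3.07, exact test, p = 0.0165). In the exact test this call ended with 500 bp windows (1.59, p = 0.0686), 3 kb windows (1.11, p = 0.657) and among genes with no close neighbour (1.86, p = 0.0522).

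**Figure D4:**
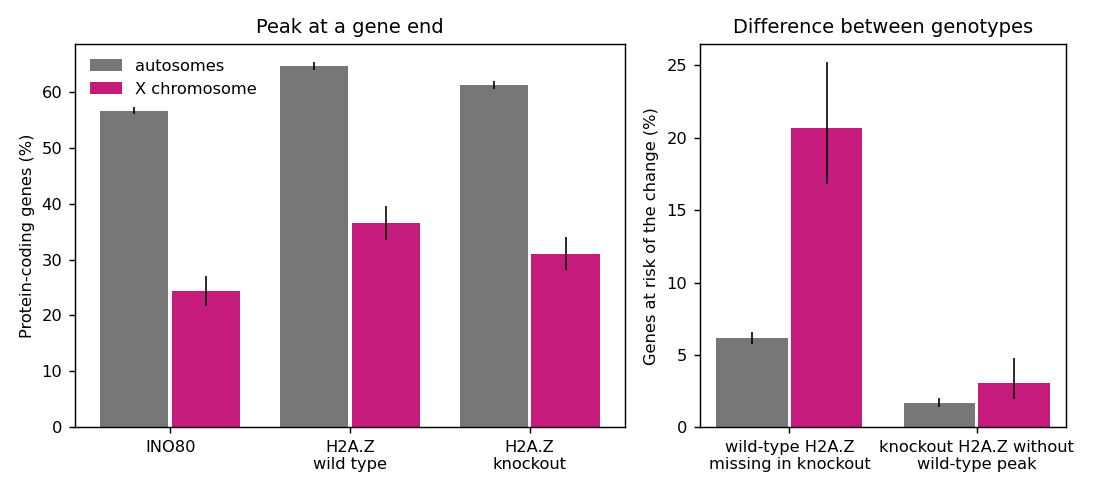
Left, percentage of autosomal (grey) and X-linked (magenta) protein-coding genes with each kind of peak at a gene end; right, percentage of genes with wild-type H2A.Z that lack it in the knockout list, and of genes without wild-type H2A.Z that have it there. Lines are 95% Wilson intervals; wild-type H2A.Z was missing from the knockout list at 20.7% of X-linked and 6.19% of autosomal genes.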

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

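All alternatives that count genes without close neighbours, genes with a partner peak outside the window or strata of width, and those of INO80 without H2A.Z, were chosen after seeing the data. Under the alternatives run, 92 values that answer a comparison kept their direction, their side of the threshold or their size, 4 lost their call, 1 reversed and 18 moved. The share of INO80 peaks at gene ends ranged from 59.4 to 73.9% and of those with wild-type H2A.Z from 79.4 to 86.1%. The odds ratio of INO80 at wild-type-only regions stayed below 1 (0.105 to 0.414), as did that at wild-type-only genes (0.109 to 0.383). The odds ratio at knockout-only genes stayed above 1 (5.72 to 27.7) against genes with H2A.Z in neither genotype, which seldom held INO80.

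Counts of regions and genes found in 1 genotype followed list length and width. With the widest 50% of each list there were 5042 wild-type-only, 11838 shared and 1152 knockout-only regions, and 1852 wild-type-only and 514 knockout-only genes. By construction, that setting leaves a peak unpartnered where its partner alone was cut. Lists of equal length gave 4841 wild-type-only and 3970 knockout-only regions, and 544 and 587 such genes. They were made by cutting the narrowest wild-type peaks, which lowers wild-type-only and raises knockout-only counts by construction. The widest 50% of the wild-type list against the full knockout list left 1256 regions and 247 genes, and the reverse left 46 regions and 18 genes. Genes without close neighbours, which are fewer by construction, gave 566 wild-type-only, 95 knockout-only and 7519 shared genes. The odds ratio of INO80 at knockout-only regions reversed to 1.48 with the width of the region in the model but not among single knockout peaks of like width (0.695); the cause was not tested. The knockout-only gain at developmental regulators made 1 list pass with 500 bp windows and 1 with 3 kb windows, against 0; the cause was not tested. INO80 without H2A.Z at developmental regulators fell to an odds ratio of 1.99 with 3 kb windows, which count more H2A.Z peaks. The X-linked excess of knockout-only H2A.Z lost its call with 500 bp windows (1.59), 3 kb windows (1.11) and genes without close neighbours (1.86); the cause was not tested. Of the values for single gene lists 171 were the same, 5 lost and 3 gained a call; where every member held a peak, 0.5 was added to each count to give a finite odds ratio.

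No paired analysis was possible because the files analysed here hold 1 list per ChIP group, so leaving out a library was not run either. The most upstream start site, base composition and motifs were not run, for want of strand and sequence. Depth is unknown, so an absent peak shows only that none was listed.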

Other observations

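The gene families, INO80 peak widths per list, repeat loci, wide lost peaks and shared-region widths described here, and INO80 without H2A.Z, were chosen after seeing the data, as were the tests of a less sensitive peak call, of INO80 at lost peaks and of peak width at X-linked gene ends, alone and with INO80.

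INO80 covered the 5S ribosomal RNA array on chromosome 8 (123538784 to 123622046), where all 41 annotated genes lay under 4 INO80 peaks of 86256 bp in total, the widest of the list, while neither H2A.Z list had a peak over any of the 41. Such repeats share reads, so this locus is uncertain. On the Y chromosome 19 of 22 INO80 peaks lay between 90740027 and 90828933, a stretch that holds the annotated pseudogene Mid1-ps1, against 1 of 9 wild-type and 0 of 2 knockout H2A.Z peaks. The lists give positions alone, so whether reads in that stretch belong to the Y chromosome alone is unknown. INO80 peaks at developmental regulators had a median width of 2906 bp against 837 bp at other genes with INO80, and those at spermatogonial genes 1973 bp against 842 bp (both adjusted p = 0.0011, from the smallest p that a permutation test with 10000 random lists can give). They were narrower at DNA repair genes (450.5 bp, adjusted p = 0.0183, permutation test) and meiotic genes (511 bp, adjusted p = 0.0390, permutation test).

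Among 12 gene families taken by name, zinc finger genes named Zfp held wild-type H2A.Z at 337 of 397 genes (84.9% against 62.2%, Fisher's exact test, adjusted p = 3.12e-22) but INO80 at 57.7% against 54.5% (exact test, adjusted p = 0.222). Proteasome genes held INO80 at 35 of 40 and mitochondrial ribosomal protein genes at 67 of 78, and olfactory receptor genes at 5 of 1110. Mage genes, many of them X-linked, had wild-type-only H2A.Z at 5 of 10 genes (exact test, adjusted p = 0.00140) and olfactory receptor genes at 9 of 26 (exact test, adjusted p = 0.000303). Neither test took peak width or INO80 into account, so neither shows a loss particular to the family. In shared regions the knockout peaks were narrower in 72.8% of 23485 regions, with median widths of 630 bp in the wild type and 488 bp in the knockout. On a log2 scale narrowing was smaller in shared regions with INO80. At gene ends the median log2 ratio of knockout to wild-type width was -0.149 with INO80 and -0.219 without it. Elsewhere these values were -0.180 and -0.383. Regions with INO80 were wider to begin with, and the medians fell by similar amounts in bp. At gene ends they went from 863 to 725.5 bp with INO80 and from 496 to 358 bp without it. Elsewhere they went from 680 to 558 bp and from 414 to 278 bp. Among regions of like width the log2 ratio was 0.112 higher with INO80 (bootstrap interval 0.0888 to 0.134), against 0.181 for the raw difference of medians. Of wild-type peaks over 719 bp, 70 of 8351 peaks with INO80 (0.838%) and 153 of 1797 without it (8.51%) lacked a knockout peak. They included those at Cldn5 and in Mast4 (chromosome 13, 102905430 to 102906789), whose nearest knockout peaks lay 34328 and 94047 bp away. Others lay close to a knockout peak, such as those at Casz1 (1915 bp, the widest) and Chat (1410 bp), with knockout peaks 388 and 149 bp away.

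Wild-type-only H2A.Z regions held INO80 less often than shared regions, an odds ratio of 0.112. Loss of whole H2A.Z peaks mainly where INO80 is bound would need an odds ratio above 1 among peaks of like width and gene-end class. The value was 0.383 (0.355 to 0.412), so such peaks were missing less often where INO80 was listed. Peaks with INO80 were wider (median 822 bp against 371 bp at gene ends), and width measures strength imperfectly. Strength that width does not capture could lower the ratio, so loss that depends on INO80 stays open. A less sensitive peak call in the knockout may contribute. Wild-type-only peaks had a median width percentile of 21.3, but knockout-only peaks had one of 14.6, so unpartnered peaks were narrow in both lists. The percentile thus does not tell which list was called less sensitively, and a general effect of the genotype could give the same. The odds ratio was 0.105 (0.0915 to 0.121) without the narrower 50% of wild-type peaks and 0.414 with width in the model. With the widest 50% of each list, which also cuts away partner peaks, it was 0.203. The part that weak peaks play thus stays open. Library depth and a general effect of the genotype on H2A.Z cannot be separated with 1 list each, and the genotype stays open. The lists hold no measure of which cells each library contained, so a difference in cell mix stays open too.

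H2A.Z was missing from the knockout list more often at X-linked than at autosomal gene ends, an odds ratio of 3.95. Neither the lower share of X-linked genes with INO80 (2.15 within genes with and without it, 1.62 to 2.85) nor multicopy families (3.47 without them, 2.498 to 4.76) accounted for it alone. Whether narrower peaks at gene ends do cannot be told apart, since width groups gave 1.70 (1.25 to 2.31) for genes and 1.21 (0.888 to 1.66) for single peaks. Narrower peaks and a lower share of genes with INO80 may together account for it. The odds ratio was 1.27 (0.931 to 1.74), an interval that includes 1 without showing equality. A test written for all X-linked peaks within width groups gave 0.597 (0.472 to 0.756) and decides nothing here, since the pattern concerns gene ends and 165 of the 520 X-linked peaks lie away from them (0.601, 0.414 to 0.870). A specific role of the silenced X chromosome was not tested, nor was its copy number taken into account.

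Developmental regulators held INO80 without H2A.Z in either genotype at 10 of 69 genes (14.5%) against 3.10% of other genes with INO80, an odds ratio of 5.29. Clustered Hox genes did not account for it, since none of the 10 was a Hox gene. Leaving Hox genes out removed only listed genes that had H2A.Z, so that test, at 6.87 (3.07 to 13.9), could not have shown otherwise. At Gata3, Pax7, Tbx5, Foxa1, Irx2, Otx2 and Wnt1, H2A.Z lay outside the 1 kb window but within 3 kb of a gene end. With 3 kb windows 3 of 69 genes remained (odds ratio 1.99, 0.398 to 6.14). Whether H2A.Z lies under the same INO80 peak, the test written for this, was not decided, since 50% of the 10 genes (23.7 to 76.3%) had it there. Pax6, Barhl1 and Lhx5, chosen after their values were seen, had no H2A.Z within 3 kb of a gene end, and Lhx5 had it further along its 7330 bp INO80 peak. No biological explanation was tested.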
